A study of Mus musculus with 2 samples.

How the data were processed

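Single-nucleus RNA sequencing reads RNA from isolated nuclei rather than whole cells. Ureters of newborn mice (postnatal day 0) were pooled by genotype, 14 mice in the DNp63cKO pool and 13 in the control pool, and 1 library was made from each pool, per the labels' protocols. Nuclei were caught in microwells with barcoded beads that carry unique molecular identifiers (UMIs), and 10000 nuclei were aimed for. The DNp63cKO mice carried a Pax2-cre driver, floxed alleles of the ΔN isoform of p63 (gene Trp63), and the R26mTmG reporter, whose fluorescent protein switches when cre has acted. The labels give the genotype of the control pool as wt, so the driver and the reporter may also differ between the pools. Pax2 is active in the nephric duct, from which the ureter epithelium grows.

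The deposited values are whole-number UMI counts per gene and nucleus, not normalized. STARsolo, STAR 2.7.11a, R 4.0.5, Seurat 4.0.5 and genome build mm10 are named per the submitters' processing notes, without their roles. The gene annotation, the filter on barcodes, the counting of introns and the exons that the deletion removes are not given in the sources used here. The lowest deposited nucleus had 500 UMIs in both libraries. Of 32589 gene IDs in the deposited count tables, 32522 were found in GENCODE M21 (GRCm38, the same assembly as mm10), which gave the coordinates.

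Nuclei with 300 or more genes and at most 5% mitochondrial UMIs were kept, 5491 of 5528 in DNp63cKO and 8889 of 9062 in control. Scrublet's automatic threshold marked 0.0546% and 0.0112% of nuclei as doublets and so had not worked. As planned for that case, the top 5% by score were removed, with ties 320 and 515 nuclei. Counts of the remaining 5171 and 8374 nuclei were scaled to 10000 per nucleus and log-transformed. Leiden clustering, which groups nuclei with similar profiles, was run at resolution 1.0 on 2000 variable genes, 30 principal components and 15 neighbours, without integration of the libraries (scanpy 1.11.5).

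The 17 clusters were named from markers fixed before the data were examined. The naming rule itself was changed after the data were seen. Under the first rule, the highest mean marker fold alone, cluster 9 was called mast cell on 1 detected marker. The rule used instead asks for 3 or more markers at 50 or more CPM and a score above 0.1, and names cluster 9 urothelium-like on 17 markers. No other name differed between the rules.

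A class was meant to be compared only if none of its clusters had more markers of another class than of its own among its 10 leading genes. Against all other nuclei, urothelium-like cluster 4 failed this check, with 0 markers of its own class and 1 each of mesothelium (Msln) and collecting duct (Scnn1b). After that failure a second reference was tried, the nuclei of other classes, under which cluster 4 had 1 marker of its own and 0 of any other class. A coarser clustering at resolution 0.1, also tried afterwards, gave 1 urothelium-like cluster of 7421 nuclei, which passed the check against all other nuclei with 2 markers of its own and 0 of another class. Of these, 7371 nuclei were among the 7411 of the 7 pooled clusters. The pooled class had been fixed before the data were examined and is reported, and because of the failed check values by numbered cluster and without cluster 4 stand beside it. The list medians by cluster were computed after the pooled ones had been seen.

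Raw UMIs were summed per class and library and divided by the class total to give CPM, the usual scale for counts of unequal totals. Deeper nuclei therefore weigh more in these values. Log2 ratios are DNp63cKO over control of CPM + 5. With 1 library per group there is no replicate and no test, so no p-value, standard error or count of changed genes is given. Intervals are exact at 95%: Poisson for CPM, conditional binomial for ratios (computed without the added 5 CPM, so that the ratio of a low gene can fall outside its interval), and Clopper-Pearson for shares. They cover counting error only and not the difference between pools. For each fixed gene list, the median log2 ratio of members with 20 or more UMIs was set among 10000 random lists of equal size matched on CPM in 20 bins, and its counting interval came from 1000 Poisson resamples. The percentile describes these 2 libraries and is not a test of genotype. Shares of nuclei with a UMI were computed after thinning each nucleus to 700 UMIs, leaving out shallower nuclei.

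Genes were named by a rule fixed beforehand: Trp63, then for each class the genes with the highest and lowest log2 ratios (12 and 12 in urothelium-like nuclei, 10 and 10 in the other classes) among those with 50 or more CPM in a library and 50 or more UMIs. A gene also had to be at least as high in the class as in all other nuclei of the library where it was higher. Mitochondrial, haemoglobin and sex-chromosome check genes and unnamed gene models were left out. Up to 4 members of each list with the largest log2 ratios could be named, and every member of the basal and superficial lists. Some genes that this rule names are not reported here.

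The functions were tested on simulated Poisson counts in which 200 genes were given known folds. The intervals assume such counts, so this checks the code and not the spread between nuclei, clusters or pools. Genes of simulated lists were drawn independently, so the lists do not stand for genes that vary together. In urothelium-like nuclei (14980 genes), intervals held the true value for 95.8% of unchanged genes, 91.9% of genes at 1.5-fold, 96.2% at 2-fold and 96.6% at 4-fold. In smooth-muscle-like nuclei (13566 genes) these shares were 95.9%, 96.6%, 96.8% and 92.4%, and in fibroblast-like nuclei (11568 genes) 96.3%, 98.2%, 94.5% and 90%. Of 100 simulated unchanged lists, 6, 4 and 6 fell outside the 95% range in the 3 classes, and 20 of 20 raised lists lay above it. In urothelium-like nuclei the added 5 CPM pulled the median estimate at 4-fold to 1.61 against a true log2 of 2. Alternatives fixed beforehand covered nucleus filters, doublets, resolution, separate clustering, variable genes, scaling (TMM in edgeR 4.0.16, and median of ratios), the added CPM, nucleus weighting, free RNA, depth and list members. Alternatives added after seeing the data were the coarse cluster, leaving out clusters 3, 4 or 9, subtracting an estimated share of free RNA, and nuclei split by Xist and Y-linked UMIs.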

Results

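The study asked what ΔNp63, the p63 isoform of basal cells in layered epithelia, does in the ureter epithelium. Nuclei of newborn mouse ureters were sequenced from 1 pool of mice with a Pax2-cre deletion of ΔNp63 (DNp63cKO) and 1 control pool. The DNp63cKO library held 5528 nuclei and 9859451 UMIs, with a median of 1298 UMIs and 984 genes per nucleus. The control library held 9062 nuclei and 16063644 UMIs, with medians of 1124.5 UMIs and 889 genes. Each group has 1 library, so every difference below lies between 2 libraries and has no replicate check.

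Urothelium-like nuclei, the epithelial lining, made up 44.0% of DNp63cKO nuclei (2277 of 5171; 95% interval 42.7 to 45.4%) and 61.3% of control nuclei (5134 of 8374; 60.3 to 62.4%). Smooth-muscle-like nuclei made up 27.9% (26.7 to 29.2%) and 22.9% (22.0 to 23.8%), and fibroblast-like nuclei 18.3% (17.2 to 19.4%) and 10.03% (9.40 to 10.7%). Endothelium-like nuclei were at 5.47% and 3.74%, pericyte-like at 1.53% and 0.908%, macrophage-like at 1.14% and 0.370%, glia-like at 0.716% and 0.454%, and neuron-like at 0.677% and 0.299%. Nephron-like nuclei numbered 12 and 3. A lower share of one class raises the shares of all others, and yield of nuclei can differ between pools. Among nuclei outside the urothelium-like class, the smooth-muscle-like share was lower in DNp63cKO, at 49.9% (48.0 to 51.7%) against 59.1% (57.4 to 60.8%), and the fibroblast-like share was 32.7% against 25.9%.

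**Figure D1:**
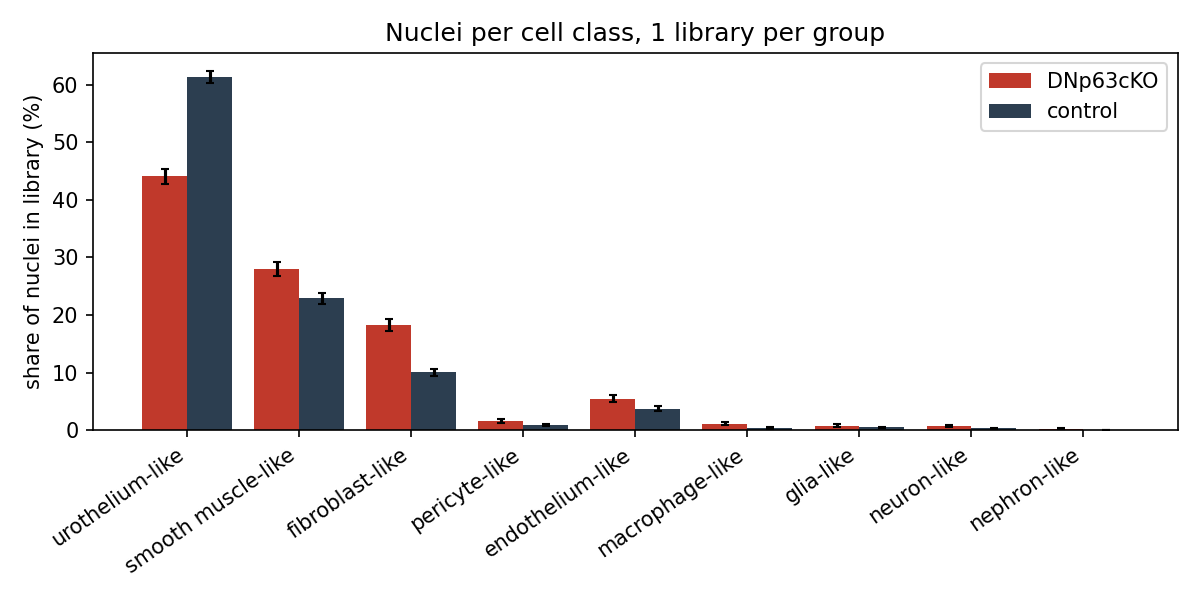
Share of nuclei (%) per cell class in the DNp63cKO and control libraries, with exact 95% binomial intervals as bars (counting error only). Urothelium-like nuclei stand at 44.0% and 61.3%.

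Within the urothelium-like class, different clusters held most of each library. Cluster 4 held 1048 DNp63cKO and 126 control nuclei, while cluster 10 held 284 and 1947 and cluster 7 held 80 and 934. Clusters 6, 8, 9 and 11 held 318 and 634, 176 and 617, 39 and 233, and 332 and 643. Cluster 4 failed the marker check that a compared class had to pass, against all other nuclei, and passed against the nuclei of other classes, a reference tried afterwards. At a coarser resolution, also tried afterwards, the class formed a single cluster that passed against all other nuclei. A cluster drawn mostly from 1 library may reflect that library rather than a cell type. Where a log2 ratio or list median of the pooled class changed sign or moved by over 1.5 times without cluster 4, its value without that cluster is therefore given too. Leaving it out removes 1048 of 2277 DNp63cKO but 126 of 5134 control nuclei. Psca, Upk3a, Sprr1a and Upk1a are among its leading genes against other classes. Cluster 7, mostly from control and with Psca and Upk1b among its own, is kept. Its nuclei had a median of 3168 UMIs, against 871 in cluster 10, and so weigh more in the class sums. Shifts without cluster 4 are thus partly by construction, and neither value is a check of the other.

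Trp63, the targeted gene (ENSMUSG00000022510, mm10 chromosome 16, 25683763 to 25892102, plus strand), stood at 137 CPM in DNp63cKO and 198 CPM in control urothelium-like nuclei, a log2 ratio of -0.51 (interval -0.66 to -0.39). It was 0.67 within cluster 4 (217 and 14 UMIs) and between -0.80 and -0.26 within each of the other clusters, and -0.12 for the class without cluster 4. Fibroblast-like nuclei, which should lack the gene, had 38.1 and 68.7 CPM, and smooth-muscle-like nuclei 28.4 and 69.5 CPM, so free RNA adds to these values. The counts join all isoforms and exons of Trp63, and UMIs tagged outside the deleted part check nothing about the deletion.

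In urothelium-like nuclei, the basal layer genes did not move together. Krt14, a basal keratin, was higher in DNp63cKO (130 against 21.5 CPM, log2 2.35), while Krt15, another basal keratin, was lower (5.32 against 23.2 CPM, log2 -1.45), as was the laminin-binding integrin Itga6 (240 against 558 CPM, log2 -1.20). These directions held within each numbered cluster with 10 or more UMIs of the gene (5 of 5, 6 of 6 and 7 of 7), with Itga6 between -2.01 in cluster 9 and -0.67 in cluster 7, and Krt14 at 2.45 in cluster 11 and 2.64 in cluster 6. Krt5 stood at 185 and 176 CPM, log2 0.07, but at 0.97 without cluster 4.

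Of 13 measured basal cell list members, 5 were higher and 8 lower, with a median log2 ratio of -0.12 (counting interval -0.20 to -0.02; percentile 7.42 among random lists). Cd44 (-0.57), Col17a1 (-0.60), Cdh3 (-0.21), Itgb4 (-0.18) and Lamb3 (-0.12) were among the lower members, and Ngfr (0.52), Pdpn (0.29) and Dst (0.01) among the higher ones. Without cluster 4 this median was 0.56, with the opposite sign, as were Cd44 (0.19), Cdh3 (0.56), Itgb4 (0.69) and Lamb3 (0.59), while Col17a1 was at -0.35, Ngfr at 0.80, Pdpn at 1.11 and Dst at 0.16. By cluster the median ran from -0.51 to 0.29, lower in 4 of 7. It was 0.02 with an estimated share of free RNA subtracted (Itgb4 0.02, Lamb3 0.08) and 0.03 in nuclei with Y-linked but no Xist UMIs (Itgb4 0.36, Lamb3 0.04).

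Of 15 superficial cell and uroplakin members, 9 were higher and 6 lower, with a median of 0.15 (0.04 to 0.25; percentile 98.4). Sprr1a (9383 against 5688 CPM, log2 0.72; its reads may be shared with related Sprr genes), Upk2 (0.49), Psca (0.42), Snx31 (0.38), Upk1a (0.27), Mal (0.24), Upk3bl (0.23), Upk3a (0.15) and Prom1 (0.13) were higher. Krt20, a keratin of surface cells, was lower (321 against 466 CPM, log2 -0.53), as were Pparg (-0.40), Grhl3 (-0.40), Fabp5 (-0.19), Rab27b (-0.06) and Upk1b (-0.04). Without cluster 4 the list median was -0.27, again with the opposite sign, as were Upk2 (-0.12), Psca (-0.27), Snx31 (-0.16), Upk1a (-0.28), Mal (-0.19) and Upk3a (-0.51), while Sprr1a was at 0.36, Upk3bl at 0.84, Prom1 at 0.46, Grhl3 at -0.86, Rab27b at -0.34 and Upk1b at -0.53. By cluster the median ran from -0.28 to 0.25, higher in 5 of 7. It was 0.31 with an estimated share of free RNA subtracted and 0.08 under median-of-ratios scaling. Upk1b was higher under a stricter nucleus filter (0.13), and with Fabp5 as a mean over nuclei (0.24 and 0.05) and with Rab27b after free RNA was subtracted (0.11 and 0.07).

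**Figure D2:**
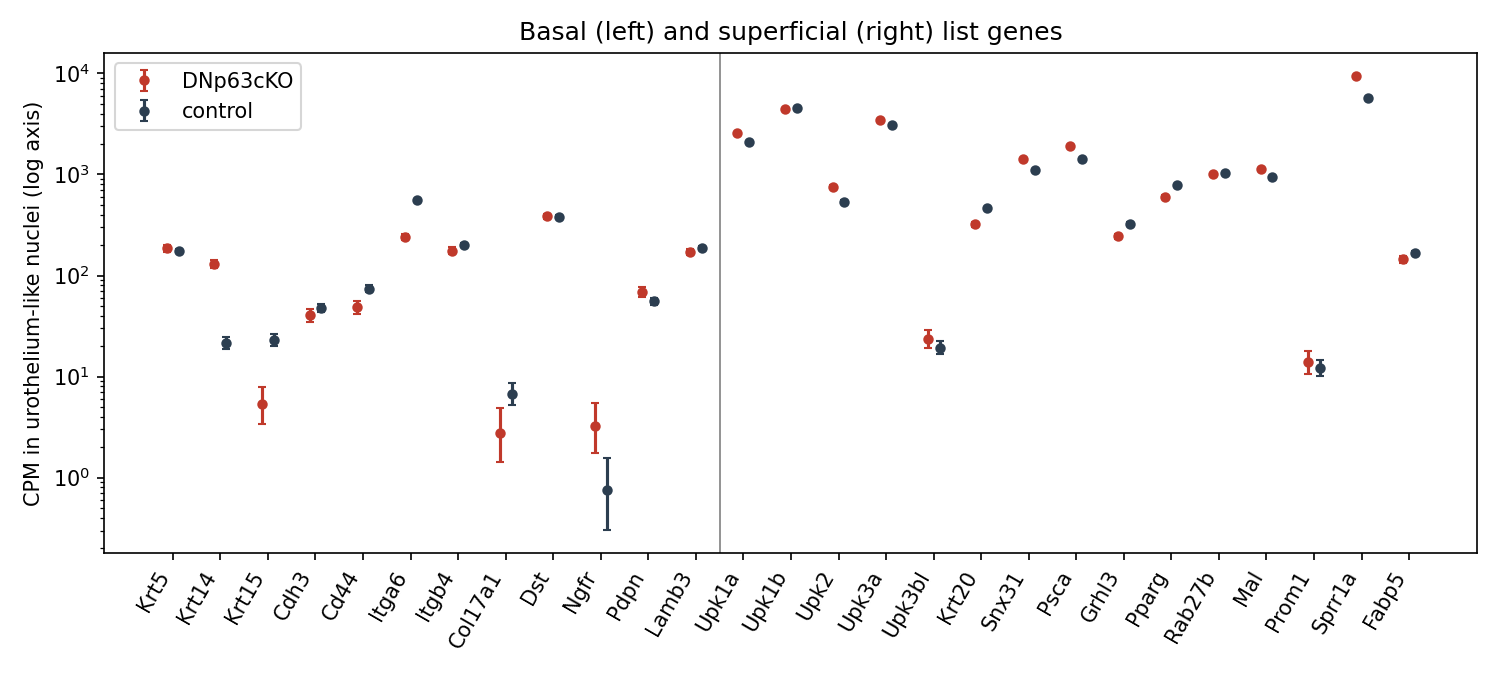
CPM on a log axis of named basal (left) and superficial (right) list genes in urothelium-like nuclei of the DNp63cKO and control libraries, with exact 95% Poisson intervals as bars. Krt14 stands at 130 and 21.5 CPM, Krt15 at 5.32 and 23.2 CPM.

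Desmosome genes, which join neighbouring cells, were lower as a group in the pooled class and in 7 of 7 clusters. The medians lay between -0.83 and -0.62 in clusters 4, 7, 8 and 9. They were weaker in clusters 6 (-0.22), 11 (-0.14) and 10 (-0.14, counting interval -0.39 to 0.01). Of 10 measured members 9 were lower, with a median of -0.41 (-0.49 to -0.35; percentile 0.01), of -0.45 without cluster 4, of -0.27 with an estimated share of free RNA subtracted, and between -0.83 and -0.14 by cluster. Examples are Pkp1 (2.31 against 16.7 CPM, log2 -1.57), Dsp (-0.56), Perp (-0.55, and -0.21 without cluster 4) and Jup (-0.52). Listed p63 targets of layered epithelia had a median of -0.38 (percentile 0; 10 of 13 lower; -0.21 without cluster 4; lower in 6 of 7 clusters), with Ripk4 at 135 against 274 CPM (log2 -0.99), Jag1 at -0.71, Fermt1 at -0.67 and Sfn at -0.65. Without cluster 4, Jag1 was at -0.23 and Fermt1 at 0.13, with the opposite sign.

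Shh, a secreted signal to the surrounding mesenchyme (ENSMUSG00000002633, mm10 chromosome 5, 28456815 to 28467256, minus strand), stood at 50.7 against 138 CPM, log2 -1.36 (-1.66 to -1.24), in the same direction in 7 of 7 clusters and at -0.75 without cluster 4. Outside the epithelium Shh stood at 11.1 against 49.2 CPM in smooth-muscle-like and 8.91 against 45.1 CPM in fibroblast-like nuclei. Free RNA can thus carry this direction into each cluster. Notch1, a receptor, was at 51.6 against 137 CPM (log2 -1.33), and Nrarp, a Notch target, at 42.8 against 127 CPM (log2 -1.46). The Notch list median was -0.22 (percentile 0.67; 6 of 10 lower) and 0.00 without cluster 4, lower in 5 of 7 clusters, and Hes1 went the other way (686 against 432 CPM, log2 0.66). The epithelial ligand list had a median of 0.09 (percentile 83.3; 10 of 16 higher), with Nrg1 at 1.44, Areg at -1.27 and Wnt4 at 0.49, the last at 0.04 without cluster 4.

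Mitosis genes were higher in all 16 measured members, with a median of 0.50 (0.43 to 0.60; percentile 100), led by Ccnb1 (0.85), Cenpf (0.71), Tpx2 (0.69) and Mki67 (143 against 88.5 CPM, log2 0.66). Without cluster 4 the median was 1.24, with Ccnb1 at 1.62, Cenpf at 1.09, Tpx2 at 1.495 and Mki67 at 1.51. It was 0.33 as a mean over nuclei, between 0.08 and 0.46 in the 6 clusters with enough members, and -0.08 in nuclei with Y-linked but no Xist UMIs, where Tpx2 was at -0.38. Cluster 6, which is led by Mki67, Top2a and Cenpf, had a median of 0.155 (0.07 to 0.27). In clusters 4, 7, 8, 10 and 11 the counting interval of the median included 0. DNA replication genes had a median of 0.07 (percentile 86.9; 12 of 16 higher), and 0.66 without cluster 4. Nephric and collecting duct genes had a median of 0.39 (percentile 99.96; 9 of 12 higher; 0.32 without cluster 4; higher in 4 of 6 clusters), with Etv4 at 1.41, Scnn1b, a sodium channel subunit, at 1.20, Pax8 at 0.98 and Scnn1g at 0.62. Without cluster 4, in which Scnn1b is a leading gene, Scnn1b was at 0.32, Scnn1g at 0.07 and Etv4 at 2.20. The list median was 0.12 in nuclei with Y-linked but no Xist UMIs.

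The remaining lists in urothelium-like nuclei had medians of -0.30 for p53 targets (percentile 0; Phlda3 -0.59), -0.27 for columnar and secretory genes (percentile 0.28; Pigr -0.87), 0.20 for immediate early and heat shock genes (percentile 99.4; Egr1 0.91, Fos -0.46), 0.13 for basement membrane genes (percentile 98.1; Nid1 1.26, Hspg2 1.23, Col4a6 -0.75) and 0.11 for oxidative phosphorylation (percentile 97.4; Cox6c 0.58). Medians were -0.10 for simple epithelium keratins (percentile 19.2; Krt7 -0.69), -0.06 for the retinoic acid pathway (percentile 19.3; Crabp2 -0.78), -0.01 for tight junctions (percentile 58.3; Cldn8 0.55) and 0.01 for inflammation and interferon genes (percentile 42.9). Without cluster 4, medians were -0.12 for p53 targets, 0.00 for columnar genes, 0.53 for basement membrane, 0.21 for oxidative phosphorylation, -0.35 for simple epithelium keratins, -0.15 for tight junctions and -0.31 for inflammation, and Phlda3 was at 0.02, Fos at -0.07, Nid1 at 1.97, Col4a6 at -0.41 and Cldn8 at 0.03. By cluster, p53 targets were lower in 6 of 7 and immediate early genes higher in 6 of 7. In nuclei with Y-linked but no Xist UMIs, the columnar median was 0.22, Phlda3 0.19 and Crabp2 0.15. The immediate early median was -0.07 after an estimated share of free RNA was subtracted.

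**Figure D3:**
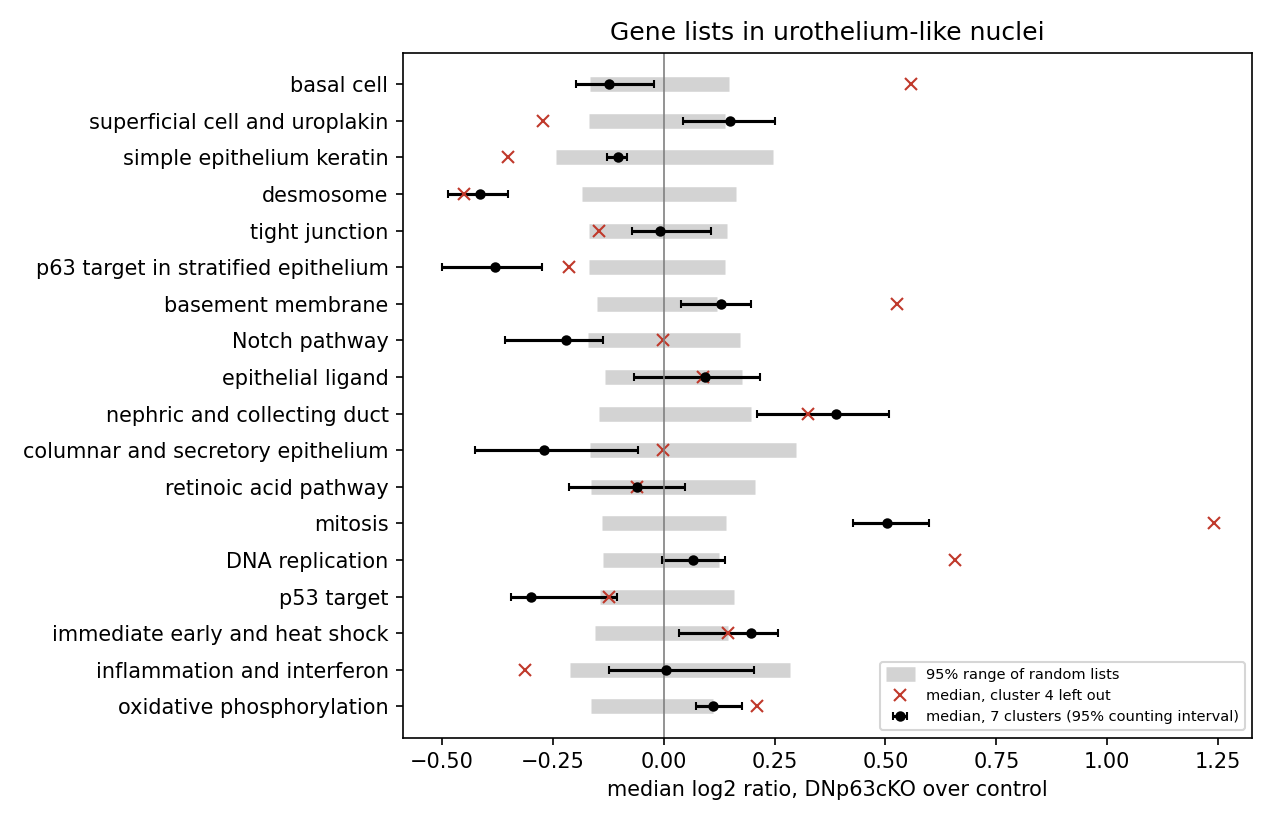
Median log2 ratio (DNp63cKO over control) of each gene list in urothelium-like nuclei, with counting intervals as bars, the 95% range of random lists in grey, and the median without cluster 4 as crosses. The desmosome list stands at -0.41 and -0.45, the basal cell list at -0.12 and 0.56.

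By size alone, the genes highest in DNp63cKO urothelium-like nuclei were Spp1 (53.4 against 0.430 CPM, log2 3.43), the carbonic anhydrase Car2 (2.68), Msln (446 against 70.3 CPM, log2 2.58), Krt14, Gsdmc2 (2.15), Olfr1459 (2.12), Gsdmc3 (1.95), Efemp1 (1.68), Camk1 (1.57), Bglap3 (1.36), Sprr2a3 (1.35) and Myo3b (1.26). Car2, Msln, Gsdmc2, Gsdmc3, Olfr1459, Bglap3 and Sprr2a3 are among the leading genes of cluster 4. Without it they were at 1.91, 1.96, 1.64, 1.28, 1.40, 0.73 and 0.62 in that order, and Myo3b was at 0.69. Of the highest genes, Gsdmc3 was higher in 5 of 7 clusters with 10 or more UMIs of the gene, Gsdmc2, Sprr2a3 and Myo3b in 6 of 7, and the others in each such cluster, of which Spp1 had 3. Gsdmc2, Gsdmc3, Bglap3 and Sprr2a3 have close relatives that can share reads and are uncertain. The lowest were Chst2 (10.9 against 100.1 CPM, log2 -2.73), Lypd3 (6.24 against 55.0 CPM, log2 -2.41), Ankfn1 (-1.92), Pla2r1 (-1.85), Slc43a2 (-1.80), Cyp4f15 (-1.79), Rgs5 (-1.73), Ivl, an envelope protein of layered epithelia (37.5 against 127 CPM, log2 -1.64), Efs (-1.61), Crim1 (-1.56), Ptpru (-1.55) and Slfn5 (-1.52). Without cluster 4, Rgs5 was at -1.02, Efs at -0.94 and Ptpru at -0.87. Each of these lowest genes but Ptpru (6 of 7) was lower in every cluster with 10 or more UMIs of the gene.

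At 700 UMIs per nucleus, 2107 DNp63cKO and 4237 control urothelium-like nuclei remained, and 170 and 897 were left out. A Krt14 UMI was seen in 7.36% (6.28 to 8.56%) and 1.39% (1.06 to 1.79%), against 1.11% and 0% of fibroblast-like nuclei. Unthinned, the urothelium-like shares were 13.1% and 2.65%. Shh was seen in 3.32% and 9.46% (fibroblast-like 0.555% and 2.74%; unthinned 7.91% and 18.2%), Trp63 in 9.78% and 14.1% (1.39% and 5.12%; unthinned 18.3% and 25.1%) and Krt15 in 0.237% and 1.72% (0.139% and 0.366%; unthinned 0.922% and 3.23%). Krt5 was seen in 10.1% of both (1.25% and 3.84%; unthinned 17.4% and 15.7%) and Krt20 in 17.1% and 22.1% (4.72% and 7.86%; unthinned 33.2% and 36.2%). Median depths were 1462 and 1226 UMIs in urothelium-like and 1037.5 and 822 in fibroblast-like nuclei.

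Uroplakin UMIs were widespread outside the epithelium. Upk1b was seen in 82.4% and 77.5% of thinned urothelium-like nuclei and in 41.2% and 42.2% of fibroblast-like ones (unthinned 90.9% and 84.3%). Upk1a was at 64.9% and 51.7% (30.4% and 22.9%; unthinned 75.7% and 59.9%), Upk2 at 30.7% and 20.9% (11.7% and 8.23%; unthinned 1123 of 2277 and 1797 of 5134 nuclei) and Upk3a at 71.3% and 65.6% (36.2% and 28.2%; unthinned 82.9% and 74.0%). Mki67 was seen in 7.93% (6.81 to 9.16%) and 5.55% (4.88 to 6.28%), unthinned 15.2% and 9.72%, and Top2a in 6.88% (5.84 to 8.05%) and 5.97% (5.28 to 6.73%), unthinned 14.7% and 11.5%. Fibroblasts also divide, so their shares of 4.85% and 4.57% for Mki67, and of 4.85% and 7.13% for Top2a, are no background for these genes.

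UMIs of both a basal list gene and a uroplakin were found in 55.1% of thinned DNp63cKO (1162 of 2107) and 67.6% of control (2864 of 4237) urothelium-like nuclei, and unthinned in 77.5% and 82.7%. After thinning, a basal gene alone was found in 4.60% and 5.29%, a uroplakin alone in 39.4% and 25.6%, and neither in 0.854% and 1.49%. Fibroblast-like nuclei had both in 24.1% and 31.6%, so co-detection includes free RNA. The basal list also holds Itga6, itself lower in DNp63cKO. Krt5 was seen in 10.1% of both and Krt14 in 7.36% and 1.39% of thinned urothelium-like nuclei. The co-detection shares can therefore not be read as shares of basal or mixed cells.

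Smooth-muscle-like nuclei, from the muscle coat around the epithelium, had lower SHH response genes in DNp63cKO. Ptch1, the SHH receptor and a target of the pathway, stood at 156 against 273 CPM (log2 -0.79, interval -0.98 to -0.64), Hhip at 117 against 192 CPM (-0.70), Smoc1 at -0.65 and Bmp4 at -0.60, each lower in 3 of 3 clusters. Of 8 measured members 7 were lower, with a median of -0.40 (-0.59 to -0.25; percentile 0), and of -0.25 under a stricter nucleus filter and -0.21 with members of 5 or more UMIs. Cluster 1 held 501 and 402 of these nuclei, cluster 2 held 498 and 770, and cluster 3, which has haemoglobin genes among its leading genes, held 444 and 742.

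**Figure D4:**
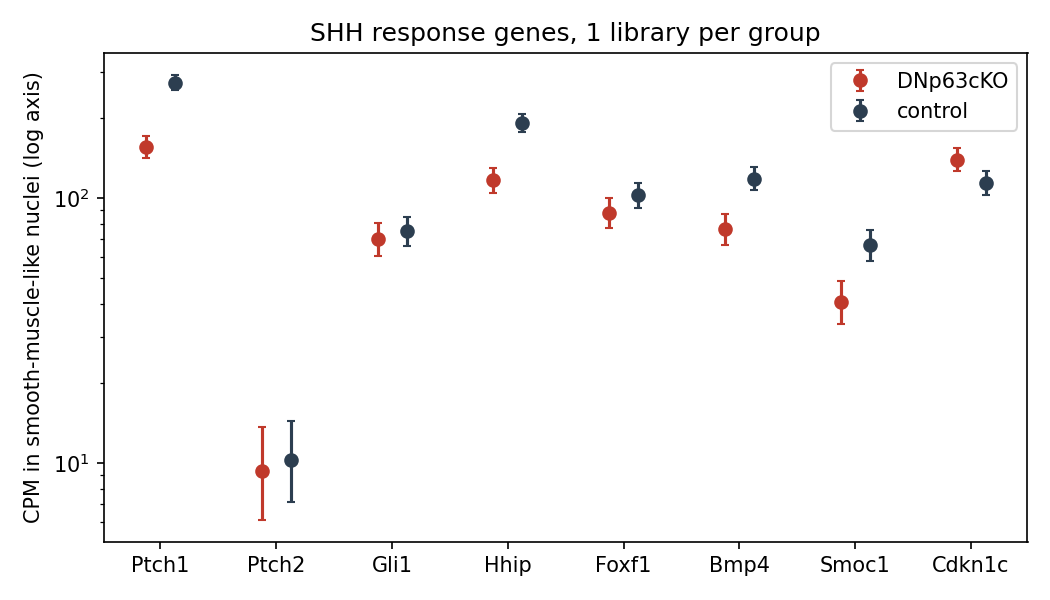
CPM on a log axis of SHH response genes in smooth-muscle-like nuclei of the DNp63cKO and control libraries, with exact 95% Poisson intervals as bars. Ptch1 stands at 156 and 273 CPM.

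Extracellular matrix genes were lower in 17 of 18 members, with a median of -0.30 (percentile 0), led by elastin Eln (74.0 against 131 CPM, log2 -0.79) and Thbs1 (-0.65), but the median was -0.05 without cluster 3, and Eln was at 0.04 under a stricter nucleus filter. WNT response genes were higher in 11 of 12 members, with a median of 0.23 (percentile 99.7; Axin2 0.61, Lef1 0.49), and -0.04 without cluster 3 and -0.08 in nuclei with Y-linked but no Xist UMIs, where Lef1 was at -0.08 and Thbs1 at 0.13. Contractile genes had a median of 0.02 (percentile 56.2; Csrp1 -0.38), and -0.13 without cluster 3, with Csrp1 at -0.24. BMP and TGFB response genes were at -0.13 (percentile 5.46; Smad7 -0.91), DNA replication at -0.17 (percentile 0.91; 0.03 in nuclei with Xist but no Y-linked UMIs), ureteric mesenchyme regulators at 0.12 (percentile 90.9; Nr2f1 0.32), the retinoic acid pathway at -0.11 (percentile 13.6), p53 targets at -0.10 (percentile 12.2), immediate early genes at -0.08 (percentile 14.9), oxidative phosphorylation at -0.06 (percentile 18.6) and mitosis at -0.01 (percentile 49.0). Inflammation genes were too few for a median: Stat2 stood at 0.21, Ifit2 at -0.15 and Nfkbia at -0.03, and without cluster 3 at 0.45, -0.06 and 0.09. Without that cluster, medians were also -0.28 for DNA replication, -0.05 for retinoic acid, -0.17 for immediate early genes, -0.19 for oxidative phosphorylation and -0.25 for mitosis.

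Highest by size in smooth-muscle-like DNp63cKO nuclei were Rps18-ps5 (1.52) and Rps27rt (1.06), which are copies of ribosomal protein genes and uncertain, Khdrbs2 (1.22), Lsamp (850 against 404 CPM, log2 1.06), Heph (1.04), Ccdc141 (0.95), Pnpla7 (0.94), Csmd1 (0.86) and Dock3 (0.84). Lowest were Enpep (38.4 against 78.8 CPM, log2 -0.95), Gas6 (-0.83), Crip1 (-0.81), Nrxn3 (-0.80), Ptch1, Eln, Kctd12 (-0.76), Mfge8 (-0.75), Efnb1 (-0.74) and Dipk2a (-0.72). Each of these genes kept its direction in 3 of 3 clusters. Without cluster 3, Rps18-ps5 was at 0.52, Rps27rt at 0.66, Heph at 0.57, Eln at -0.08 and Bmp4 at -0.98.

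Fibroblast-like nuclei also had lower matrix genes, with 15 of 18 members lower and a median of -0.31 (percentile 0; Fmod -0.98, Thbs2 -0.63, Eln -0.63). SHH response genes had a median of -0.19 (percentile 5.24; 4 of 8 lower), with Hhip at 38.9 against 71.0 CPM (-0.79) and Ptch1 at 154 against 224 CPM (-0.53). BMP and TGFB response genes were at -0.19 (percentile 1.72; Smad6 -0.65; list 0.32 in nuclei with Y-linked but no Xist UMIs), contractile genes at 0.11 (percentile 93.9), WNT response at 0.07 (percentile 68.5), immediate early genes at 0.18 (percentile 92.9), retinoic acid at 0.15 (percentile 87.0), mitosis at 0.13 (percentile 83.7), DNA replication at -0.14 (percentile 5.30), p53 targets at -0.07 (percentile 23.6), oxidative phosphorylation at -0.06 (percentile 18.8) and mesenchyme regulators at 0.00 (percentile 48.4). Of the inflammation genes, Stat2 stood at 0.18 and Nfkbia at -0.06.

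By size, Mgat4c (365 against 130 CPM, log2 1.46), Sphk1 (1.09), Ctnna2 (1.03), the growth factor Nrg1 (94.8 against 45.1 CPM), Avl9 (0.99), Zbtb16 (0.95), Amigo2 (0.93), Rnf123 (0.93), Mrps17 (0.93) and Tsc2 (0.92) were highest in fibroblast-like DNp63cKO nuclei. Thbd (17.0 against 50.7 CPM, log2 -1.34), Klf2 (-1.12), Fat3 (-1.11), Crip1 (-1.03), Rbsn (23.5 against 51.8 CPM), Rab8b (-0.99), Sema6c (-0.90), Syndig1 (-0.86), Nrk (-0.86) and Frmd5 (-0.85) were lowest. In nuclei with Y-linked but no Xist UMIs, Syndig1 was at 0.72 and the matrix gene Fmod at 0.04. Thbd rests on 21 and 45 UMIs, so its interval is wide.

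The pools differed in sex-linked RNA. Xist, made from an inactive X chromosome, stood at 1182 against 1442 CPM in urothelium-like nuclei (log2 -0.29, and -0.06 without cluster 4) and Y-linked Ddx3y at 95.3 against 60.7 CPM (log2 0.61). Free RNA of uroplakins was also unequal: the 4 uroplakins in fibroblast-like nuclei reached 38.5% of their mean level in the DNp63cKO library and 28.6% in control. The estimated share of free RNA rests on these 4 genes alone. In fibroblast-like nuclei Krt5 stood at 20.3 against 49.6 CPM and Sprr1a at 2086 against 1353 CPM. Over all nuclei they stood at 98.5 against 136 CPM and 5561 against 4211 CPM. Relative to all nuclei, Sprr1a thus went the same way as the uroplakins and Krt5 the other way.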

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

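The settings that left out cluster 3, 4 or 9, used the single cluster at resolution 0.1, subtracted an estimated share of free RNA or split nuclei by sex-linked UMIs were chosen after the data were seen. Under the 17 settings planned beforehand, 3694 gene values stayed within their counting interval, 306 moved outside it and 5 changed sign, while 669 list medians stayed, 41 moved and 0 changed sign. Under the 7 added ones, 818 gene values stayed, 328 moved and 52 changed sign, and 124 list medians stayed, 60 moved and 8 changed sign. For 13 genes whose ratio lay outside its interval because of the added 5 CPM, the interval was extended to the ratio, so a small shift can count as moved. They make up 92 of the 306 and 38 of the 328. A change of sign was counted only for genes whose counting interval lay on one side of 0 and for lists outside the 95% range of random lists. Other values whose sign changed, 23 of genes and 37 of lists under the planned settings and 32 and 27 under the added ones, are among those that stayed or moved. The cause was not tested for any change below, except that a larger added CPM shrinks ratios by construction. Leaving out cluster 4 also shifts values partly by construction, since it removes many more DNp63cKO than control nuclei. Nuclei with Y-linked UMIs are few, so their values are imprecise. No paired analysis was possible because each group has 1 library.

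The share of urothelium-like nuclei in DNp63cKO was 41.7% with doublets kept and 42.0% at resolution 2.0. In control it was 59.2% with doublets kept, 51.7% at resolution 2.0 and 67.2% under the filter of 500 genes and 1% mitochondrial UMIs. Co-detection of basal and uroplakin UMIs was 77.5% and 82.7% without thinning, and 33.8% and 36.4% at 350 UMIs, both over all 2277 and 5134 nuclei and not the 2107 and 4237 kept at 700 UMIs.

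In urothelium-like nuclei, Shh was at -1.16 with an added 20 CPM, -0.75 without cluster 4, -1.19 with estimated free RNA subtracted and -1.04 in Y-linked nuclei. Trp63 was at -0.38 at resolution 2.0, -0.12 without cluster 4, -0.34 with estimated free RNA subtracted and -0.20 in Y-linked nuclei. The basal cell median was 0.56 without cluster 4, 0.0242 with estimated free RNA subtracted and 0.0294 in Y-linked nuclei. The superficial cell median was -0.27 without cluster 4, 0.31 with estimated free RNA subtracted and 0.25 in Xist nuclei. The desmosome median was -0.32 as a mean over nuclei, -0.27 with estimated free RNA subtracted, -0.50 in Xist nuclei and -0.29 in Y-linked nuclei. Mitosis stood at 0.40 with an added 20 CPM, 0.33 as a mean over nuclei, 1.24 without cluster 4, 0.62 with estimated free RNA subtracted, 0.71 in Xist nuclei and -0.0845 in Y-linked nuclei. The SHH response median in smooth-muscle-like nuclei was -0.25 under the stricter filter, -0.60 with members of 100 or more UMIs and -0.21 with members of 5 or more.

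By that condition, signs changed in urothelium-like nuclei without cluster 4 for Cd44 (0.19), Cldn23 (-0.15), Fermt1 (0.13), Foxj1 (0.0890), Gins1 (0.21), Itgb4 (0.69), Lamb3 (0.59), Mal (-0.19), Phlda3 (0.0202), Psca (-0.27), Snx31 (-0.16), Upk1a (-0.28), Upk2 (-0.12) and Upk3a (-0.51). Outside it they also changed for Cdh3 (0.56) and the basal cell and inflammation (-0.31) lists. As a mean over nuclei, which gives each nucleus the same weight, 65 gene values of this class stayed, 51 moved and 2 changed sign. These 2 were Fabp5 at 0.0459 and Upk1b at 0.24. Under the stricter filter, Upk1b was at 0.13. With estimated free RNA subtracted, Itgb4 was at 0.0242, Krt19 at 0.0619, Lamb3 at 0.0822, Rab27b at 0.0749, Upk1b at 0.11 and the immediate early list at -0.0741. In Y-linked nuclei, Crabp2 was at 0.15, Itgb4 at 0.36, Lamb3 at 0.0355, Mcm6 at -0.12, Phlda3 at 0.19, Sesn2 at 0.0607, Sox9 at 0.36, Top2a at -0.0072, Tpx2 at -0.38 and the columnar list at 0.22.

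In smooth-muscle-like nuclei, signs changed by the same condition without cluster 3 for Col14a1 (0.0740), Cox7c (-0.0229) and the WNT response list (-0.0365), and under the stricter filter for Cox7c (-0.0374) and Eln (0.0447). Outside it they also changed without cluster 3 for Nfkbia (0.0920) and the contractile list (-0.13). In Xist nuclei they changed for Bbc3 (-0.0192), Mcm5 (0.0887) and the DNA replication list (0.0314). In Y-linked nuclei they changed for Cox7c (-0.13), Crabp2 (0.29), Dhrs3 (0.30), Gata2 (-0.11), Hells (0.0347), Lef1 (-0.0786), Thbs1 (0.13), Zmat3 (1.10) and the WNT response list (-0.0815). In fibroblast-like nuclei, Cox6c was at -0.43 and Tpm2 at -0.34 with estimated free RNA subtracted. Y-linked fibroblast-like nuclei had Cdkn1c at 1.02, Cox6c at -0.08, Dmd at -0.32, Fmod at 0.0442, Id4 at -0.32, Mcm3 at 2.32, Mcm6 at -1.77, Syndig1 at 0.72, Tpm2 at -0.0338, Trp63 at 1.27 and the BMP and TGFB list at 0.32.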

Other observations

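The tests of less SHH and of free RNA in the SHH pattern, of the mix of smooth-muscle-like and of urothelium-like clusters and of escape from the deletion were chosen after their results had been seen, and the others before. Among nuclei outside the urothelium-like class, macrophage-like nuclei made up 2.04% in DNp63cKO and 0.957% in control, and endothelium-like nuclei 9.78% and 9.66%. Uroplakin UMIs reached 79.7% of the library's mean level in pericyte-like and 81.3% in glia-like DNp63cKO nuclei, against 29.2% and 37.2% in control. Xist was at -0.40 and Ddx3y at 0.79 in fibroblast-like nuclei, and at -0.04 and 0.11 in smooth-muscle-like nuclei, as log2 ratios of DNp63cKO over control. In smooth-muscle-like nuclei the Y-linked genes Uty, Eif2s3y and Kdm5d were at 0.43, 0.63 and 0.60. Without cluster 3, Xist was at -0.38 and Ddx3y at 0.72 there.

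SHH response genes were lower in smooth-muscle-like nuclei (median -0.40) of the library whose epithelium had less Shh RNA (-1.36), and a hypothesis is that less SHH from the epithelium may lower them, but in fibroblast-like nuclei, which it would also reach, the median of -0.19 (-0.46 to 0.06; random lists -0.23 to 0.23) decides nothing. With the 3 clusters at the same shares in both libraries the median was -0.37 (-0.59 to -0.27; random lists -0.19 to 0.14), and within clusters 1, 2 and 3 it was -0.35, -0.44 and -0.35 over all 8 members, or -0.65, -0.62 and -0.35 over members with 20 or more UMIs in the cluster (7, 7 and 8), with each interval below 0, which argues against the mix of clusters as the whole cause, although a bound of -0.20 set beforehand for each cluster was not met over all members in clusters 1 and 2 (intervals up to -0.06 and -0.17). With an estimated share of free RNA subtracted, for which the library's mean profile was assumed, the median was -0.44 (-0.63 to -0.23), but this interval reaches into the range of random lists under the same subtraction (-0.26 to 0.22), and the contractile median of 0.0172 was -0.13 without cluster 3, so dilution by free RNA cannot be told apart. Nuclei matched for sex-linked UMIs had medians of -0.36 (-0.66 to -0.18) and -0.45 (-0.80 to 0.01), whose intervals are too wide to set the sex mix aside. With 1 library per group, genotype itself was not tested.

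Krt14 was higher while Krt15 and Itga6 were lower in urothelium-like DNp63cKO nuclei. In 18 of 18 pairs of a gene and a cluster with 10 or more UMIs the direction was that of the pooled class. Free RNA can carry a library's direction into each cluster, so this alone cannot set the mix of clusters aside. Outside the epithelium, Krt14 was at 15.8 against 5.44 CPM in smooth-muscle-like nuclei, and Itga6 at -1.31, -1.26 and -0.88 in their clusters 1, 2 and 3. For Krt14, the ratios of 2.64 and 2.45 in clusters 6 and 11, where it is a leading gene against other classes, argue against the mix alone. Several intervals for Krt15 include 0, and the clusters were formed on the same counts. The Krt14 ratio was 2.11 in Xist nuclei and 2.98 in Y-linked nuclei, which argues against the sex mix. Whether the Krt14 UMIs come from nuclei that escaped the deletion cannot be told apart, since Trp63 counts (-0.51) join all isoforms and exons. No biological explanation was tested, since an effect of the loss of ΔNp63 needs replicate pools of each genotype.

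Mitosis genes were higher in urothelium-like DNp63cKO nuclei (median 0.50). At 700 UMIs per nucleus an Mki67 UMI was still seen in 7.93% against 5.55%, which argues against depth alone, though at 350 UMIs, with no nuclei left out, the intervals overlapped (4.83%, 3.99 to 5.79%, and 3.56%, 3.07 to 4.11%), as they did for Top2a at 700 UMIs (6.88% and 5.97%). The lower median under TMM and median-of-ratios scaling was 0.44, which argues against scaling by the class total as the whole cause. These scalings shifted log2 ratios in the class by only -0.06 and -0.07, however, and the median was lower still as a mean over nuclei. The median was 0.71 (0.62 to 0.86) in Xist nuclei but -0.0845 (-0.36 to 0.06) in Y-linked nuclei. The Y-linked value met the bound set beforehand for the sex mix of the pools. That mix alone would leave no difference within Xist nuclei, so their value argues against it as the whole cause. The difference may hold in nuclei of one sex only. The mix of clusters was not tested for this pattern. Cluster 6, led by Mki67, Top2a and Cenpf, held 318 of 2277 DNp63cKO and 634 of 5134 control nuclei. Within it the median was 0.155. A difference in cell division between the genotypes therefore stays one of several open explanations.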
